A study of Mus musculus with 4 samples.

How the data were processed

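Left ventricles of 12-month-old mice of strain 129 were snap frozen, total RNA was extracted with Trizol and mRNA libraries that keep no strand were sequenced, per the labels' protocols. The series describes 3 pooled samples for each strain and time, and 1 library per genotype and time was used here. Whether 3 mice or 3 libraries were pooled is not stated, so p-values measure only the spread between these 4 libraries, which may be technical. The authors deposited whole-number read counts for 35275 genes, aligned to mm10 per the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here. Counts of overlapping, antisense and near-identical genes are uncertain because the library keeps no strand and the counting rule is not given.

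The deposited FPKM values equal the count divided by the file's gene length and by the library total (largest relative difference 4.96e-12), per the file headers and a check of the values. The deposited log2 fold changes and p-values are the authors' own comparisons of 2 single libraries, and the test behind them is not given in the sources used here. A further 20 columns of per-sample values in that table were not used. Gene symbols and coordinates were taken from the files, and 34490 of the identifiers were found in the reference table of names.

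Groups came from the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes were kept by filterByExpr with the additive design, which left 13296 genes with 99.9% of the reads. Counts were scaled by TMM. The tests of time and of genotype came from 1 additive fit of genotype and time (edgeR quasi-likelihood, robust, Benjamini-Hochberg threshold 0.05). This fit has 1 residual degree of freedom per gene, so the spread is largely shared over genes, and the residual holds the genotype-by-time difference together with the spread between libraries. Standard errors of the fit are the log2 fold divided by the root of the F statistic.

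Comparisons with 1 library per group give log2 ratios of TMM-scaled CPM with a prior count of 2, for genes with at least 100 reads in the higher library (for the genotype-by-time difference, a mean of at least 50 reads). Their 95% intervals are exact conditional binomial intervals and, like the floor of 3 reads for a gene without reads, cover counting error only. Before the data were examined, the design, the alternatives, 29 gene lists, 20 marker lists and the rule for named genes were fixed. That rule takes the 12 largest log2 folds in each direction among genes that passed, with the same direction in both pairs of libraries and a mean of at least 1 CPM, and for single-library comparisons the 6 largest in each direction. Genes without a symbol, predicted genes, Rik genes and pseudogenes are counted but not named. Of each list 2 to 4 members are named, and of the clock lists any. A list's named members are those past the threshold with the largest absolute log2 fold, or, where none passed, the largest among those with at least 50 reads. Members that passed only when adjusted over the list alone, and genes named for a single value beside these, were chosen after their values were seen. A list's median was placed among 10000 random lists of the same size matched in 10 bins of mean expression.

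Alternatives were other scalings, filters, tests (DESeq2, limma-voom and limma on log2 of FPKM plus 0.1 or 1), the fit without the other factor, and leaving out each library in a fit that also drops the other factor, where the arm with 1 library is assumed to vary like the other. Chosen after seeing the data were edgeR without its legacy mode and offsets from a smooth trend on GC content and length of each gene's longest GENCODE M21 transcript, available for 99.6% of the genes tested. The additive fit was tested on simulated counts with 200 changed genes. For PM against AM over 13077 genes it recovered 63% of 100 genes changed 2-fold and 98% of 100 changed 4-fold, with 6 false calls. For dKPQ against WT over 13053 genes it recovered 46% and 96%, with 6 false calls. The simulated counts varied by the trended dispersion alone. They held no genotype-by-time difference, no trend on GC content or length and no difference in composition between libraries. Recovery and false calls in the real libraries may therefore differ from these values.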

Results

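RNA from the left ventricle of 12-month-old mice of strain 129 was sequenced in 4 libraries. They covered wild-type (WT) mice and mice heterozygous for an Scn5a allele, called dKPQ here, that lacks the residues lysine, proline and glutamine of the cardiac sodium channel. Each genotype had 1 library labelled AM and 1 labelled PM, which the series relates to the phase transitions of the light cycle without saying which label belongs to which. Totals were 17298438 counts in WT AM, 15858461 in dKPQ AM, 18246994 in WT PM and 14119965 in dKPQ PM. The dKPQ PM library stood apart. It had 16309 genes with a read against 17143 to 17266 in the others, and a TMM scaling factor of 0.855 against 1.05 to 1.07. Mitochondrially encoded genes took 18.8% of its counts and 12.0% to 16.4% of the counts of the others, and haemoglobin genes took 1.07% against 0.445% to 0.693%.

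Scn5a, which encodes the pore-forming subunit of the cardiac sodium channel (chromosome 9, 119483408 to 119579016 on the reverse strand, mm10), was read at similar levels in the 4 libraries, with 142 counts scaled to library size (CPM) in WT AM, 123 in dKPQ AM, 121 in WT PM and 124 in dKPQ PM. Its log2 fold was -0.08 ± 0.23, adjusted p = 0.995 for dKPQ over WT and -0.11 ± 0.23, adjusted p = 0.954 for PM over AM, neither of which passed the test. The allele is a small in-frame deletion, so a gene-level count does not check the genotype labels. None of the 17 measured sodium channel genes and regulators passed between the genotypes (edgeR, 0 over all genes, 0 adjusted over the list alone and 1 at an unadjusted p below 0.05; DESeq2 and limma-voom also gave 0), with Scn4b at 0.77 ± 0.37, adjusted p = 0.715.

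The first comparison asked which ventricular genes differed between the PM and AM libraries in both genotypes. Genes of the circadian clock were among the most changed. Arntl, the activator that pairs with Clock to drive the clock, fell by 4.50 on the log2 scale at PM (SE 0.41, adjusted p = 2.58e-24), from 13.4 to 0.669 CPM in WT and from 15.9 to 0.580 in dKPQ. Its partners Npas2 (-2.43 ± 0.52, adjusted p = 8.12e-04) and Clock (-1.19 ± 0.27, adjusted p = 0.00269) fell as well. The period genes Per2 (2.25 ± 0.38, adjusted p = 1.55e-06), Per3 (1.84 ± 0.33, adjusted p = 1.28e-05) and Per1 (1.67 ± 0.23, adjusted p = 1.12e-09), which repress that activator, rose together with the clock-driven transcription factor Dbp (2.60 ± 0.24, adjusted p = 2.94e-23). Values after ± are standard errors of the additive fit, with n = 2 libraries per arm, unless another source is named.

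**Figure D1:**
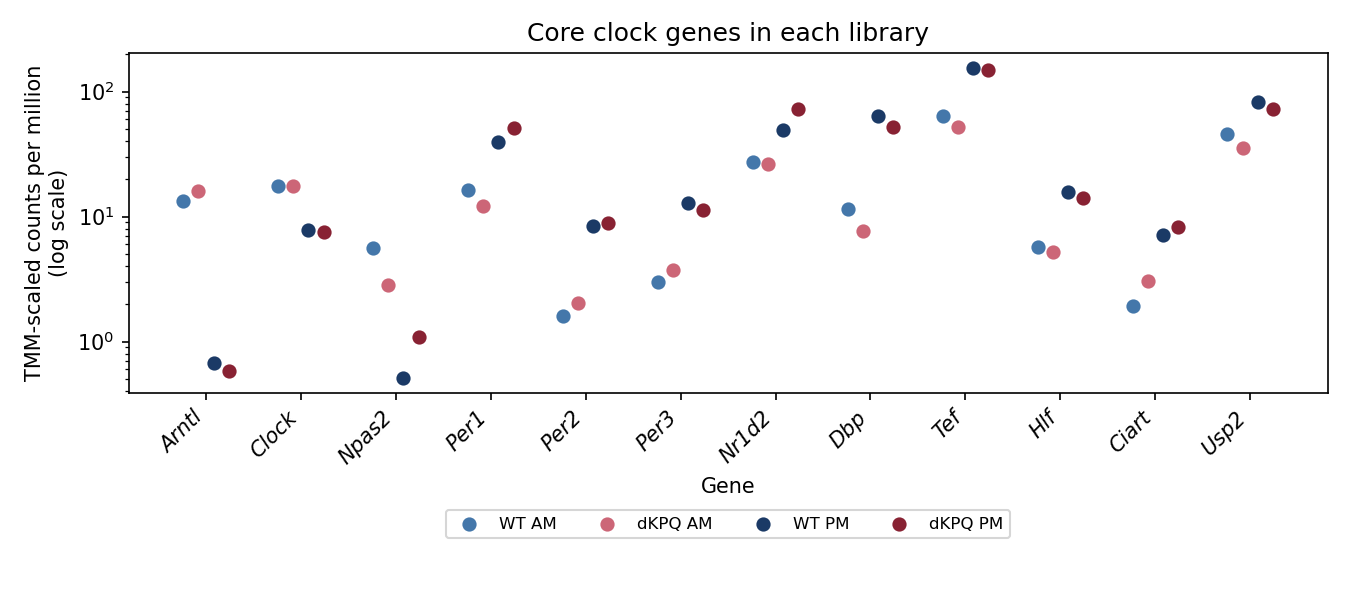
TMM-scaled CPM (vertical log axis) of 12 clock genes (horizontal axis) in the 4 libraries, 1 point per library and no error bars because each group is 1 library. Arntl lies at 13.4 and 15.9 in the AM libraries and at 0.669 and 0.580 in the PM libraries, while Dbp lies at 11.5 and 7.69 at AM and at 63.6 and 51.8 at PM.

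Of the 13 measured genes of the clock repressor arm and direct clock outputs, 9 rose, 0 fell and 4 did not pass, and the count adjusted over the list alone was also 9. Beside the genes above, these were Nr1d2 at 1.14, the PAR bZIP factors Hlf at 1.46 and Tef at 1.39, Ciart at 1.65 and the deubiquitinase Usp2 at 0.95. Of the 7 measured genes in the list of the activator arm and genes with its phase, 0 rose and 3 fell. Adjusted over the list alone 1 rose (Cry1, listed for its phase and not as an activator) and 4 fell. Nr1d1, a repressor of Arntl, had -0.41 ± 0.25, adjusted p = 0.698 and did not pass. In the repressor and activator lists DESeq2 gave 7 and 1 calls and limma-voom 9 and 3.

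In all, 126 of 13296 genes passed between PM and AM (edgeR quasi-likelihood test, adjusted p below 0.05), 66 higher and 60 lower at PM, and 125 of them had the same direction in both genotypes. Passing largely selects for a shared direction, since the residual holds the genotype-by-time difference, and over all genes tested 55.3% shared it. The named genes with the largest rise included the folate enzyme Mthfd1l (2.58 ± 0.53, adjusted p = 4.00e-04), Cyp2e1 (2.34 ± 0.42, adjusted p = 2.09e-05), Sfrp5 (1.96 ± 0.46, adjusted p = 0.00504) and Tspan4 (1.71 ± 0.23, adjusted p = 1.23e-10). Spon2 (-2.70 ± 0.32, adjusted p = 3.94e-14), the collagen gene Col5a3 (-2.34 ± 0.28, adjusted p = 2.31e-13), the metalloprotease Adam19 (-2.23 ± 0.30, adjusted p = 3.42e-10) and Slc41a3 (-2.17 ± 0.23, adjusted p = 5.43e-17) fell. Smaller falls were found in Tmem171 (-1.79), Colq (-1.76), Clmp (-1.74) and the transcription factor Creb3l1 (-1.67), with adjusted p between 9.07e-04 and 0.00623. With DESeq2, 11 of the 24 genes named by the rule for time still passed and 13 did not, Mthfd1l and Sfrp5 among the latter. With total counts as the only scaling, the median of all genes moved to -0.14 and the calls were 31 higher and 54 lower.

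Of the 15 measured glucocorticoid response genes, 4 rose, 1 fell and 10 did not pass, and adjusted over the list alone 10 rose and 1 fell. The metallothionein Mt2 (1.69 ± 0.24, adjusted p = 2.88e-09), Zbtb16 (1.39 ± 0.38, adjusted p = 0.0315), Tsc22d3 (0.86 ± 0.23, adjusted p = 0.0192) and Per1 rose, and the cell cycle inhibitor Cdkn1a (-1.36 ± 0.23, adjusted p = 3.54e-06) fell. Of the 17 measured immediate early genes, 0 rose and 2 fell, Nr4a1 (-1.40 ± 0.27, adjusted p = 8.79e-05) and Egr1 (-1.37 ± 0.31, adjusted p = 0.00225), and adjusted over the list alone 1 rose and 4 fell. In the hypertrophy list of 14 genes, the natriuretic peptide gene Nppb (-1.47 ± 0.29, adjusted p = 1.64e-04) and the calcineurin regulator Rcan1 (-1.05 ± 0.23, adjusted p = 0.00122) fell and Mt2 rose, and adjusted over the list alone 1 rose and 4 fell. The median of the hypertrophy list was 0.01 in WT (7 of 14 above 0) and -0.61 in dKPQ (3 of 14 above 0). Among 11 oxidative stress genes, Gsta3 (1.06 ± 0.24, adjusted p = 0.00208) and Gclm (0.93 ± 0.23, adjusted p = 0.00826), both of glutathione metabolism, rose and 0 fell, with the same counts adjusted over the list alone. Herpud1 rose in the unfolded protein response list (1.05 ± 0.24, adjusted p = 0.00267), where 2 rose adjusted over the list alone, and Ifi27l2a rose in the interferon list (0.87 ± 0.22, adjusted p = 0.0150), where 1 rose adjusted over the list alone. In the glucocorticoid, hypertrophy and unfolded protein lists DESeq2 gave 3, 3 and 1 calls and limma-voom 4, 3 and 1. In the immediate early, oxidative stress and interferon lists DESeq2 gave 0 and limma-voom 2, 2 and 1.

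Of 21 fibrosis and matrix genes, 3 fell at PM, namely the matrix protease Mmp14 (-1.62 ± 0.26, adjusted p = 6.18e-07), Col1a1 (-1.13 ± 0.23, adjusted p = 4.17e-04) and Col5a1 (-0.94 ± 0.25, adjusted p = 0.0181), and 5 fell adjusted over the list alone. In WT alone the log2 ratios of Col1a1 and Col5a1 were -0.44 and -0.30, and in dKPQ they were -1.90 and -1.68. The endothelial receptor Kdr fell (-1.14 ± 0.23, adjusted p = 3.48e-04) while 7 of the 8 endothelial markers did not pass, and the count adjusted over the list alone was also 1. The heat shock genes Hspa1a (-1.69 ± 0.45, adjusted p = 0.0241) and Hspa1b (-1.49 ± 0.36, adjusted p = 0.00826) fell. They are near-identical copies whose reads cannot be assigned with certainty, and their level was highest in WT AM, with 19.0 CPM of Hspa1b against 1.49 to 4.84 elsewhere. In the matrix, endothelial and heat shock lists DESeq2 gave 1, 1 and 0 calls and limma-voom 2, 1 and 2.

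Markers of other tissues moved with time as well. Of 7 measured white fat markers 4 rose, among them Cidec (2.36 ± 0.46, adjusted p = 1.03e-04), the adipokine gene Adipoq (1.88 ± 0.46, adjusted p = 0.00826) and Cfd (1.90 ± 0.26, adjusted p = 3.10e-10), and 4 rose adjusted over the list alone. Of 6 measured atrial markers 3 rose, Mybphl (2.87 ± 0.60, adjusted p = 5.36e-04), Sln and the atrial light chain Myl4 (1.85 ± 0.25, adjusted p = 3.13e-10), and 3 rose and 1 fell adjusted over the list alone. The Sln level went from 6.53 to 47.1 CPM in WT, while in dKPQ it had 3 reads at AM and 0 at PM. In the fat and atrial lists DESeq2 gave 1 and 0 calls and limma-voom 3 and 4. The median of 5 atrial markers, without Sln, was 2.48 in WT and -0.69 in dKPQ. Within dKPQ the log2 ratios of PM to AM were 0.91 for Myl4, unlike that median, and -0.62 for Hspa1a. Fits with a library left out used time alone and so compared unequal mixes of the genotypes, and there Hspa1a had 0.58 without WT AM, while without WT PM Myl4 had -1.13, Mybphl 0.18 and Cfd 0.46, of which none passed. Mybphl had 154 reads in WT PM and 15, 3 and 7 in WT AM, dKPQ AM and dKPQ PM, and the ratio of Cfd within dKPQ was 2.28. The X-inactivation transcript Xist fell (-2.45 ± 0.39, adjusted p = 1.55e-06), from 137 to 4 reads in WT and from 233 to 73 in dKPQ. It passed with limma-voom and not with DESeq2.

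The count of changed genes between PM and AM was 37 with DESeq2, 78 with offsets for GC content and transcript length chosen after seeing the data, and 20 without genotype as a term, where 9 of the 24 genes named by the rule still passed. With a library left out and genotype also dropped as a term it was 18 without WT AM, 18 without dKPQ AM, 2039 without WT PM and 144 without dKPQ PM, with 11, 11, 17 and 17 of the named genes in that order, and the effect of the library was not separated from that of the missing term.

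The second comparison asked which genes differed between dKPQ and WT ventricles at both times. Of the 6 measured atrial markers 5 fell in dKPQ, and single fat and heat shock transcripts fell as well. Sln, an inhibitor of the calcium pump that is abundant in atrial muscle, had 3 reads in the dKPQ libraries together and 1034 in the WT libraries (118 at AM and 916 at PM), 264-fold lower in scaled counts (95% counting interval 90.02 to 1281). The atrial light chain Myl4 (-3.69 ± 0.26, adjusted p = 1.02e-40), the fat-derived factor Cfd (-2.24 ± 0.26, adjusted p = 3.71e-14) and the heat shock gene Hspa1a (-2.77 ± 0.46, adjusted p = 5.08e-06) fell. At AM alone, with 1 library per genotype, the log2 ratios of Myl4, Cfd and Hspa1a were -2.84, -2.59 and -3.17, and that of Sln was -4.47 (95% counting interval -7.48 to -3.60). None of the 20 genes named by the rule for this comparison still passed without time as a term, where 0 genes passed in all, and none of them changed sign under any alternative.

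In all, 46 of 13296 genes passed between dKPQ and WT, 14 higher and 32 lower in dKPQ, each with the same direction at both times. Passing largely selects for a shared direction here too, and over all genes tested 51.0% shared it. With total counts as the only scaling, the median of all genes moved to -0.15 and the calls were 4 higher and 32 lower. The atrial count adjusted over the list alone was also 5, and the genes that fell included Mybphl (-3.26 ± 0.62, adjusted p = 2.61e-04), Dkk3 (-1.55 ± 0.34, adjusted p = 0.00409) and the natriuretic peptide gene Nppa (-1.17 ± 0.27, adjusted p = 0.0200). The log2 ratio of Dkk3 was -0.36 at AM and -2.77 at PM. Myl7, an abundant atrial light chain, had 465 and 3781 reads in WT AM and WT PM and 37 and 13 in dKPQ AM and dKPQ PM, and its fit gave -5.35 ± 1.95, adjusted p = 0.952. Of 7 white fat markers 2 fell, Cfd and the carbonic anhydrase gene Car3 (-2.002 ± 0.28, adjusted p = 5.86e-09), and 6 fell adjusted over the list alone. Of 6 smooth muscle markers Myh11 fell (-0.91 ± 0.24, adjusted p = 0.0472), 3 fell adjusted over the list alone, and the smooth muscle genes Actg2 (-2.34 ± 0.59, adjusted p = 0.0299) and Lmod1 (-1.82 ± 0.42, adjusted p = 0.0105) outside the list fell too. In the atrial, fat and smooth muscle lists DESeq2 gave 1, 2 and 0 calls and limma-voom 6, 2 and 0.

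**Figure D2:**
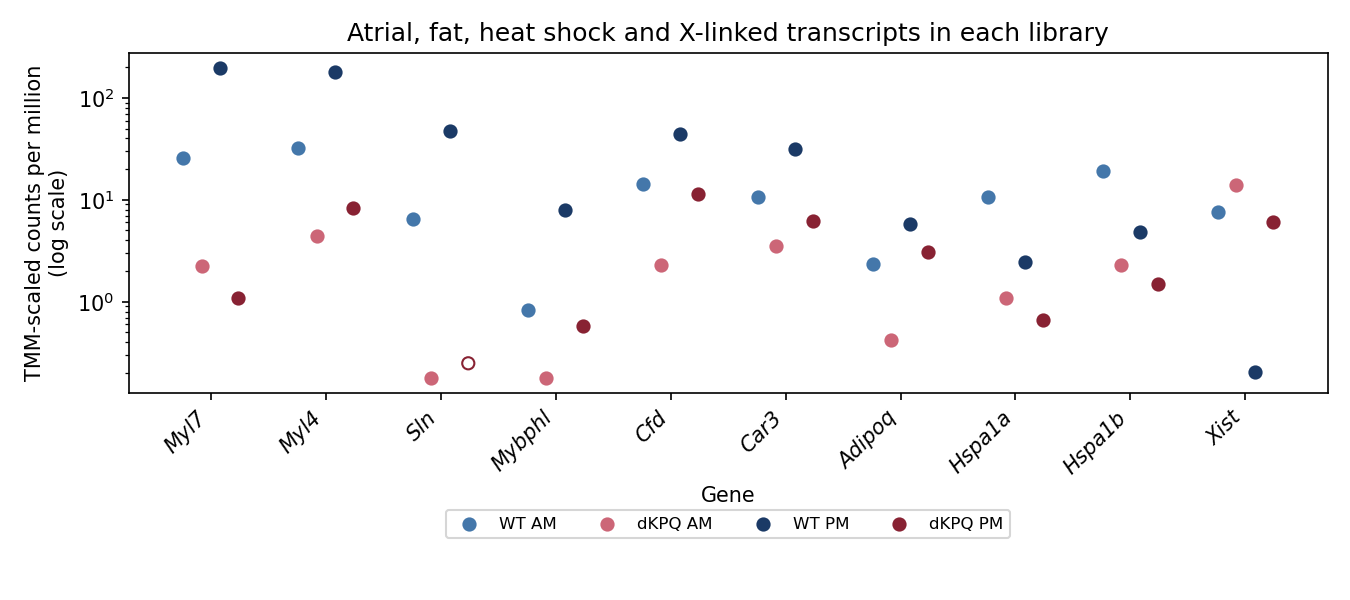
TMM-scaled CPM (vertical log axis) of atrial (Myl7, Myl4, Sln, Mybphl), fat (Cfd, Car3, Adipoq), heat shock (Hspa1a, Hspa1b) and X-linked (Xist) transcripts in the 4 libraries, 1 point per library. The open circle stands for 0 reads of Sln in dKPQ PM and is drawn at the level of 3 reads as an upper limit, and Myl7 lies at 195 in WT PM and 1.08 in dKPQ PM.

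Among 17 heat shock genes the near-identical Hspa1a and Hspa1b (-2.49 ± 0.37, adjusted p = 6.13e-08) fell and 15 did not pass (list median -0.19), and 5 fell adjusted over the list alone. Of 21 fibrosis and matrix genes Col1a1 fell (-1.15 ± 0.23, adjusted p = 0.00116) and 20 did not pass, while 10 fell adjusted over the list alone, among them Fmod (-1.66) and Cilp (-1.48). At AM the log2 ratio of Col1a1 was -0.46 and at PM it was -1.92. Nr4a1 (-1.23 ± 0.27, adjusted p = 0.00449) was the immediate early gene that fell, with 3 adjusted over the list alone, and Mt2 (-0.92 ± 0.24, adjusted p = 0.0417) fell in the glucocorticoid list, with 2 adjusted over the list alone. In the hypertrophy list Nppa, which is also an atrial marker, and Mt2 fell, and 5 fell adjusted over the list alone. The median of that list was -0.06 at AM (8 of 14 below 0) and -0.77 at PM (12 of 14 below 0). Kcne4, a potassium channel accessory subunit (-1.81 ± 0.47, adjusted p = 0.0378), and Ltbp2, a matrix protein gene (-1.55 ± 0.36, adjusted p = 0.0116), also fell. DESeq2 gave 1 call in the heat shock list and 0 in the matrix, immediate early, glucocorticoid and hypertrophy lists, and limma-voom gave 2, 1, 1, 0 and 1 in that order.

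Fewer named genes rose in dKPQ. They were Xist (2.04 ± 0.38, adjusted p = 4.84e-04), the mitochondrially encoded mt-Nd4l (1.62 ± 0.34, adjusted p = 0.00212), the calmodulin-binding Nrgn (1.35 ± 0.36, adjusted p = 0.0477), Triqk (1.29 ± 0.33, adjusted p = 0.0362), the kinase gene Rps6ka5 (1.29 ± 0.34, adjusted p = 0.0498), alpha-synuclein Snca (1.09 ± 0.29, adjusted p = 0.0495), Znhit3 (1.08 ± 0.24, adjusted p = 0.00779) and Klhl9 (0.88 ± 0.23, adjusted p = 0.0498). The mt-Nd4l gene abuts other mitochondrial genes and the rule for counting shared reads is not given, so its count is uncertain. Of the 12 measured mitochondrially encoded genes it alone rose, and 2 rose adjusted over the list alone, with a list median of 0.46 (0.15 at AM and 0.79 at PM). DESeq2 gave 0 higher and 4 lower genes in dKPQ, limma-voom 12 and 23, and offsets for GC content and transcript length 1 and 12. None of the named genes that rose passed with DESeq2 or with the offsets. With limma-voom 6 of all 20 named genotype genes, risen or fallen, did not pass, and Xist was among them. Apart from mt-Nd4l, the log2 ratios of these risen genes were larger at PM than at AM, as for Znhit3 with 0.28 at AM and 1.84 at PM.

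None of the 20 measured clock genes passed between the genotypes with edgeR, DESeq2 or limma-voom, 0 passed adjusted over each list alone, and 0 had an unadjusted p below 0.05. Over all genes 840 had such a p. These fits test a difference shared by both times, so opposite differences at AM and PM could be missed. Npas2 had a log2 ratio of dKPQ to WT of -0.96 at AM (47 against 101 reads) and 0.92 at PM (13 against 10). Its ratio of PM to AM was -3.17 in WT and -1.30 in dKPQ. List medians of dKPQ against WT were -0.005 at AM and -0.07 at PM for the activator arm, and -0.14 and -0.11 for the repressor arm. Each group here is 1 library, so this was not tested. None of the 21 listed potassium channel genes, 77 genes within 5 Mb of Scn5a or 22 fatty acid oxidation genes passed with these tools, nor did any adjusted over each list alone, and 1, 9 and 5 of them had an unadjusted p below 0.05 in edgeR. Kcne4, which passed in edgeR, is not in the potassium channel list. The median of the fatty acid oxidation list was 0.32, at percentile 100 of random lists matched on expression, but -0.03 at AM (8 of 22 above 0, percentile 52.66) and 0.59 at PM (20 of 22 above 0). That of the matrix list was -0.52, at percentile 0, with -0.26 at AM and -0.82 at PM, as a description of these libraries. With a library left out and time also dropped as a term, the genotype count was 12 without WT AM, 6 without WT PM, 1062 without dKPQ AM and 3 without dKPQ PM, where 7, 4, 10 and 0 of the 20 named genes still passed. It was 4 with DESeq2 and 13 with offsets for GC content and transcript length, chosen after seeing the data.

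Each genotype was next set against the other at each time, with 1 library per group and so no replicate check. At AM, 53 of 9312 genes differed at least 2-fold, 33 higher and 20 lower in dKPQ. The mesothelial marker Upk3b had a log2 ratio of 1.71 (95% counting interval 1.39 to 2.08) followed by mt-Nd4l at 1.60 (95% counting interval 1.20 to 2.08) and the nuclear RNA Neat1 at 1.45 (95% counting interval 1.38 to 1.53). Lowest were Sln at -4.47 (95% counting interval -7.48 to -3.60), Myl7 at -3.46 (95% counting interval -4.06 to -3.05) and Hspa1a at -3.17 (95% counting interval -4.09 to -2.60). These intervals cover counting error only.

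At PM, 359 of 9310 genes differed at least 2-fold, 138 higher and 221 lower in dKPQ. Sln had 0 reads in dKPQ PM and 916 in WT PM, at least 189.5-fold lower against a floor of 3 reads in that library. Myl7 followed at -7.34 (95% counting interval -8.41 to -6.72) and Myl4 at -4.41 (95% counting interval -4.73 to -4.14). Highest were Nrgn at 2.05 (95% counting interval 1.63 to 2.58), Triqk at 2.04 (95% counting interval 1.70 to 2.44) and Rps6ka5 at 1.92 (95% counting interval 1.51 to 2.43). With total counts as the only scaling the count was 695. The haemoglobin and mitochondrial shares of dKPQ PM given above stand beside all of these values.

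Within WT, 93 of 9462 genes differed at least 2-fold between PM and AM, 60 higher and 33 lower at PM. The atrial genes Mybphl, Myl7 and Sln led the higher genes, with Myl7 at 2.91 (95% counting interval 2.78 to 3.06) and Sln at 2.83 (95% counting interval 2.57 to 3.14), and Dbp stood at 2.45 (95% counting interval 2.25 to 2.69). Xist at -4.56 (95% counting interval -7.10 to -3.81), Arntl at -4.10 (95% counting interval -5.25 to -3.52) and Npas2 at -3.17 (95% counting interval -4.54 to -2.50) were lowest. Within dKPQ, 471 of 9062 genes differed at least 2-fold, 209 higher and 262 lower at PM. Dbp stood at 2.73 (95% counting interval 2.48 to 3.04), Per1 at 2.05 (95% counting interval 1.83 to 2.29) and Pfkfb1, a regulator of glycolysis, at 1.95 (95% counting interval 1.59 to 2.38), and Arntl was lowest at -4.52 (95% counting interval -6.11 to -3.72), followed by Spon2 at -3.03 (95% counting interval -3.85 to -2.46). With total counts as the only scaling the dKPQ count was 803.

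**Figure D3:**
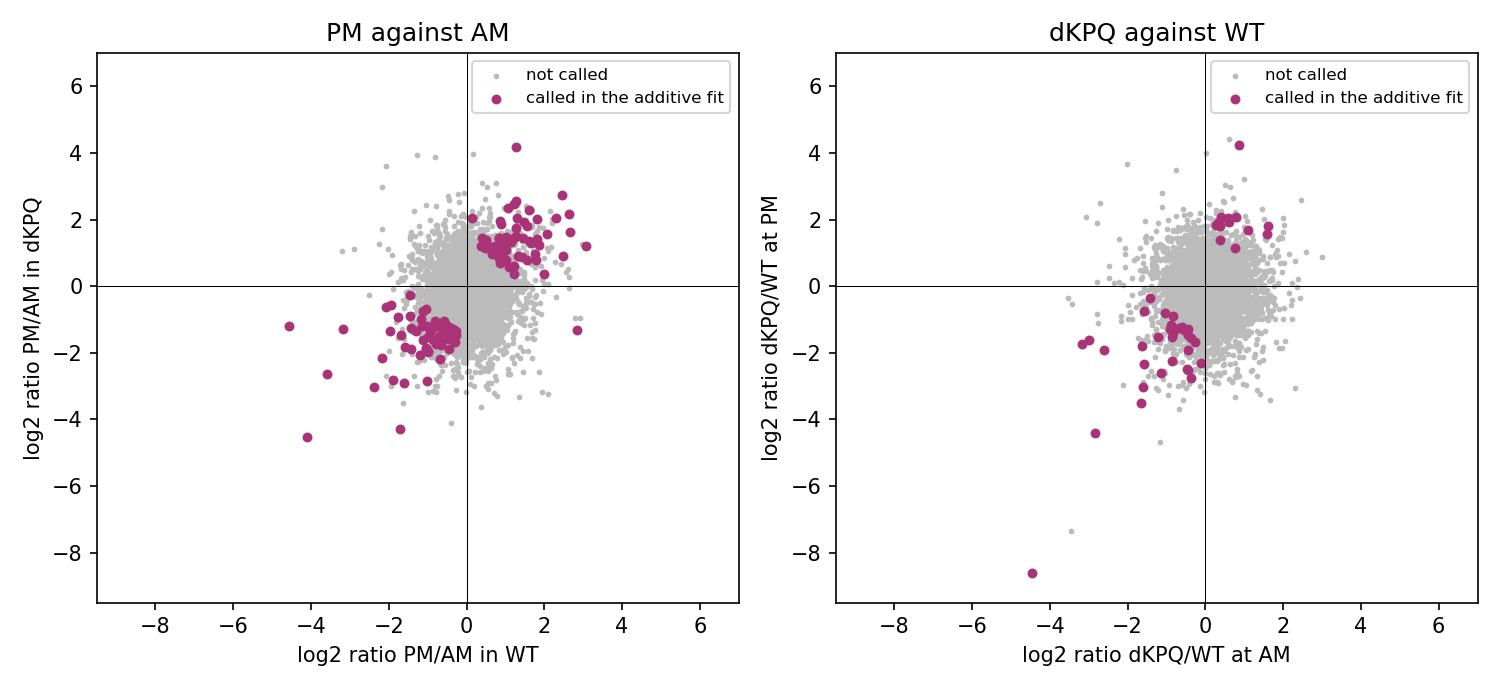
For 13296 genes (1 point each), the left panel sets the log2 ratio of PM to AM in WT (horizontal) against that in dKPQ (vertical), the right panel sets the log2 ratio of dKPQ to WT at AM (horizontal) against that at PM (vertical), and coloured points passed the test in the additive fit. Of these, 125 of 126 in the left panel and 46 of 46 in the right have the same sign on both axes. Passing largely selects for this, since the residual of the fit holds the difference between the pairs. Over all genes shown, 55.3% in the left panel and 51.0% in the right have the same sign.

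Across all genes tested, which are not independent replicates, the log2 ratios of PM to AM in WT and in dKPQ had a Pearson r of 0.13 and a Spearman rho of 0.14. For the ratios of dKPQ to WT at AM and at PM these were 0.07 and 0.05. Over the 3508 genes with a mean of at least 32 CPM they were 0.31 and 0.28 for time and 0.25 and 0.16 for genotype.

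The log2 change with time in dKPQ minus that in WT describes these libraries only. With 1 library per group no test was possible, and the dKPQ PM library, which stood apart, enters every value. A difference between the genotypes in time course was therefore not shown. The absolute value of this log2 difference reached 1 in 713 of 10485 genes, 288 positive and 425 negative. Among the most negative were the atrial light chain Myl7 (-3.88), Rfx1 (-2.83) and the phosphatase gene Inpp5d (-2.59), and Sln went from 118 to 916 reads in WT and from 3 to 0 in dKPQ, too few there for a fold. Among the most positive were Xist (3.37) and the haemoglobin gene Hbb-bs (2.32), one of several similar copies. The fat gene Cidec went from 45 to 121 reads in WT and from 2 to 51 in dKPQ. The endothelial list had a median of -0.77 and the erythroid list of 1.72. With total counts as the only scaling the count was 1226.

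The authors' deposited table compares single libraries. Per the authors' deposited table, 9 genes had an adjusted p below 0.05 between WT and dKPQ at AM and 62 at PM. The authors' deposited table gives 23 such genes between PM and AM in WT and 71 in dKPQ. The threshold of 0.05 was applied here. The significance flag in the authors' deposited table marked fewer genes, 7 and 17 between WT and dKPQ at AM and PM. It marked 14 and 20 between PM and AM in WT and dKPQ. Such p-values compare the libraries, not the conditions.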

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

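The tests of equal atrial levels in the WT libraries and of Xist were chosen after the result was seen, and so were the offsets for GC content and length. The remaining tests were written down before their results. The following genes had log2 ratios of PM to AM of opposite sign in the genotypes, each of at least 0.5 in size, and the difference was not tested because each group is 1 library. The values are the log2 ratio in dKPQ minus that in WT. They were 2.32 (-0.55 in WT and 1.77 in dKPQ) for Hbb-bs, 2.02 (-0.77 in WT and 1.24 in dKPQ) for Pirt, 1.89 (-1.01 in WT and 0.88 in dKPQ) for Zxdb and 1.88 (-0.80 in WT and 1.09 in dKPQ) for Senp8. They were -3.88 (2.91 in WT and -0.97 in dKPQ) for Myl7, -2.49 (0.73 in WT and -1.75 in dKPQ) for Vgll2 and -2.45 (1.47 in WT and -0.98 in dKPQ) for Lrrn4cl. The median of these per-gene differences over 5 atrial markers, without Sln because it had at most 3 reads in either dKPQ library, was -2.20 (separate medians of 2.48 in WT and -0.69 in dKPQ) and that over the erythroid list 1.72 (separate medians of -0.79 in WT and 0.85 in dKPQ).

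Sln, Myl7, Myl4 and Mybphl were low in both dKPQ libraries and uneven between the WT libraries. Dkk3 was lower in dKPQ mainly at PM, with a log2 ratio to WT of -0.36 at AM and -2.77 at PM. The median log2 ratio of WT PM to WT AM over the atrial list was 2.66, which is part of the pattern and so excludes no effect of genotype. Sln and Myl7 kept nearly the same ratio of reads in WT AM (0.254) and WT PM (0.242), a value not among the tests written down beforehand. Other markers moved less alike. The log2 ratio of WT PM to WT AM was 2.83 for Sln and 2.91 for Myl7, but 2.48 for Myl4, 3.08 for Mybphl and 1.71 for Dkk3. A further 8 atrial genes, listed without seeing their values, had a median genotype log2 fold of -0.51 (percentile 0.05 of matched random lists), with 7 of 8 below 0 and 0 past the test. This is consistent with different amounts of atrial tissue in the WT libraries as a candidate explanation, although the median log2 ratio of WT PM to WT AM over those 8 genes was only 0.24 and 5 of the 8 had at least 1 CPM in both dKPQ libraries. A genotype effect, equal at both times or not, and atrial gene expression within the ventricle, stay open as untested.

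More genes differed at least 2-fold between the genotypes at PM (359) than at AM (53), and thinned to the same total these were 333 and 47, so lower depth does not account for the difference. The tests here were set up for genotype calls that rest on dKPQ PM, which was not shown, because the fit without that library also dropped time. GC content and transcript length explained 21.0% of the variance over genes in dKPQ PM, but 24.3% in dKPQ AM. The requirement set beforehand, a larger share in dKPQ PM than in any other library, was thus not met. Each library was set against the mean of the others, so these shares are not independent and do not show which library held the bias. Offsets for this bias moved the median absolute log2 fold of the 46 called genes from 1.28 to 1.15 and their median SE from 0.29 to 0.28. All 46 kept their sign, but only 11 still passed. Fewer non-myocyte cells in dKPQ PM may add to the difference at PM. After the offsets, endothelial markers there had a median of -0.51 ± 0.07 (SE) and smooth muscle markers of -0.55 ± 0.17. The highest of 5 medians, that of pericytes, was -0.00111 ± 0.17. These SEs measure the spread between the marker genes within dKPQ PM, not the spread between libraries. Without the offsets, the smooth muscle median for dKPQ against WT was -0.46 at AM and -0.51 at PM. Within dKPQ it was -0.13 for PM against AM, so low smooth muscle markers were not particular to dKPQ PM. The endothelial medians in that order were 0.08, -0.61 and -0.68. With 1 dKPQ library at PM this bias, the cell makeup and an effect of genotype at PM cannot be told apart.

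Xist varied from 4 reads in WT PM to 233 in dKPQ AM, while Y-linked genes were read in all 4 libraries, at 82.1 to 142 CPM. If the libraries held different shares of female mice, Y-linked reads could be expected to fall where Xist is high, but the library with most Xist had 1.11 times the Y-linked CPM of the library with least (95% counting interval 1.04 to 1.18). This test was first set against counting error, under which the explanation would have been excluded, and after the result was seen that criterion was replaced by the spread between libraries (a factor of 1.26), because Y-linked levels differed 1.73-fold over the libraries. Under the later criterion different shares of female mice stay open. For Xist no biological explanation, such as an effect of genotype, was tested.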

How the results depend on the processing

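The offsets for GC content and length and edgeR without its legacy mode were chosen after seeing the data. The count of 126 genes between PM and AM stayed within 1.5 times under the other scalings, filters, limma-voom, both FPKM settings, edgeR without robust moderation and edgeR without its legacy mode. The genes themselves changed more than their count. With total counts alone 71 of 85 calls were among the 126, and with FPKM plus 0.1 and 1 these were 73 of 109 and 75 of 111. The count was 37 with DESeq2, 20 without genotype as a term and 78 with the offsets, of which 74 were shared. Leaving out single libraries gave 18 to 2039. The count of 46 genes between dKPQ and WT was 4 with DESeq2, 0 without time as a term (471 at an unadjusted p below 0.05), 85 and 94 with limma on log2 of FPKM plus 0.1 and 1, and 13 with the offsets. Among the 46 were 30 and 32 of the calls with FPKM plus 0.1 and 1, and 21 of 36 calls with total counts alone. Leaving out single libraries gave 3 to 1062. FPKM keeps only the library total as scaling. Each fit with a library left out also dropped the other factor, so its count does not show the effect of that library alone. Without dKPQ PM, 0 of the 20 named genotype genes and 17 of the 24 named time genes still passed, but with all libraries and the other factor dropped 0 and 9 did.

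Counts of genes at least 2-fold apart without the read minimum were 519 and 1172 between the genotypes at AM and PM, 506 and 1433 between the times in WT and dKPQ, and 1751 for the genotype-by-time difference, since more genes enter. With total counts alone and with log2 of FPKM plus 0.1 they were 695 and 628 between the genotypes at PM, 803 and 711 between the times in dKPQ, and 1226 and 1088 for the difference. The highest over the lowest library of Scn5a was 1.18 in scaled counts and 1.40 in FPKM. Over all alternatives for named genes, 513 values kept their direction and their side of the threshold, 232 no longer passed and 2 reversed, namely Myl4 between PM and AM without WT PM (-1.13, with up to 4.43 when another library was left out) and Hspa1a without WT AM (0.58, with down to -3.15 when another was left out). These 2 values compare unequal mixes of the genotypes, and within dKPQ the log2 ratios were 0.91 and -0.62, in the direction of the calls. Of the values for lists 209 were kept, 50 moved and 1 reversed, the ribosomal protein median between the genotypes with total counts alone (-0.031). Nearly all are medians, and the rest are counts of lists at the extremes of the random lists. A median was kept if it moved by no more than the SD of its medians in the separate pairs. Lists that differed most between the pairs were thus kept most easily. With 1 residual degree of freedom and 14119965 to 18246994 counts per library, genes near the read minimum give wide intervals.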

Other observations

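Of the ribosomal protein genes none of 86 passed with edgeR, DESeq2 or limma-voom (0 adjusted over the list alone, 11 at an unadjusted p below 0.05 in edgeR), but their median log2 fold was 0.34 (percentile 100) among random lists matched on expression, a description of these libraries. In WT alone the median was 0.11 and in dKPQ 0.56, where the dKPQ PM library stood apart and the deviation of a library from the others followed transcript length in opposite directions (Spearman rho 0.50 in dKPQ AM and -0.35 in dKPQ PM). Each deviation is from the mean of the other libraries, so a trend in 1 library pushes the others the opposite way. The opposite signs are therefore not independent. The cholesterol synthesis list had a median of -0.28 (percentile 1.8; -0.27 in WT and -0.08 in dKPQ), with 2 genes that fell adjusted over the list alone, Sqle and Hmgcs1, and 0 of 14 over all genes with the same tools (4 at an unadjusted p below 0.05 in edgeR). In the Scn5a neighbourhood the chemokine receptor gene Cx3cr1 was the 1 of 77 that fell at PM (-1.66 ± 0.43, adjusted p = 0.0166), and DESeq2 and limma-voom gave 0 there.

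Erythroid markers had a median genotype log2 fold of 0.47 (percentile 99.98), but of -0.59 at AM (0 of 6 above 0, percentile 0) and 1.42 at PM (6 of 6 above 0), with 0 of 6 past the test with the same tools (2 at an unadjusted p below 0.05 in edgeR) and 1 that rose adjusted over the list alone, Alas2. Of the Y-linked genes Ddx3y had a genotype log2 fold of 0.81 ± 0.22, adjusted p = 0.0632 and did not pass over all genes, while 1 rose adjusted over the list alone. Of 7 mesothelial markers 0 passed with the same tools (1 at an unadjusted p below 0.05 in edgeR), and Upk3b rose adjusted over the list alone, with a list median of 0.59 (percentile 99.33), but of 1.01 at AM (7 of 7 above 0) and -0.53 at PM (2 of 7 above 0).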
